A study of Homo sapiens with 23 samples.

How the data were processed

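RNA was measured in 23 libraries of SUDHL5 cells treated with CDK-TCIP1, with the compounds Neg1 or Neg2, or with DMSO. Per the labels' protocols, cells were kept in RPMI-1640 with fetal bovine serum, plated with compound or DMSO, and lysed in TRIsure. RNA was purified on columns with DNase I, enriched for poly(A) RNA and sequenced in paired ends on an Illumina NovaSeq. Per the submitters' processing notes, FastQC, cutadapt, kallisto and DESeq2 were used. Their versions, the transcript set and the strand setting are not given in the sources used here.

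The authors deposited, for each library, the table that kallisto writes, with estimated counts and TPM for each of 227912 transcripts. An estimated count shares a read among the transcripts it matches, so genes that overlap or have near-identical copies hold less certain values. The deposited TPM values were used only in the length-scaled alternative described below. Transcript identifiers were matched, without their version numbers, to the GENCODE 29 annotation of GRCh38, which may not be the annotation the authors used. Of the transcripts, 205964 matched. Those without a match held 1.16 to 1.28% of the counts of a library and were left out of gene totals and tests. Estimated counts were summed over the transcripts of each of 58592 genes and then rounded to whole numbers. Coordinates are those of the same annotation, and symbols are the current ones for its gene identifiers (58201 genes had one).

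Groups were taken from the sample titles, and all 23 libraries had a group. There were 3 DMSO libraries, harvested at 4 h. CDK-TCIP1 was given for 2 h at 10 nM (2 libraries), 30 nM (4 libraries) and 100 nM (3 libraries), and for 4 h at 30 nM (3 libraries). Neg1 and Neg2 at 30 nM had 2 libraries each at 2 h and at 4 h. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Vehicle was harvested at 4 h alone, so a comparison of a 2 h group with DMSO differs in time as well as in compound.

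Library totals ran from 17396484 to 26373153 estimated counts. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom of 4.31 to 14.2 over genes with at least 20 counts in a pair, and none was counted as a repeat of another. Genes too low for the filterByExpr rule of edgeR were removed, which left 17743 genes. The main test was the edgeR quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3), with TMM normalization. A single fit held all 23 libraries, with a coefficient for each group and 14 residual degrees of freedom. The common biological coefficient of variation was 0.099. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene is described as called, or as having risen, fallen or changed, where the adjusted p was under 0.05. Fold changes are on the log2 scale. They are relative to the bulk of genes, which TMM sets to no change, so a shift of all mRNA together would not show. Their standard error is the size of the fold change divided by the square root of its F statistic. Principal components and gene list tests used log2 CPM with a prior count of 2. Levels are in CPM, counts scaled to the library size after TMM, with the standard deviation over the libraries of a group.

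The comparisons, the tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. Comparisons were CDK-TCIP1 against DMSO at each dose and time, CDK-TCIP1 against Neg1 and against Neg2 at the matched dose and time, Neg1 and Neg2 against DMSO and against each other, 4 h against 2 h, both dose steps at 2 h, and the difference over time of the effect of CDK-TCIP1 against the mean of Neg1 and Neg2. Genes were named by a fixed rule. It took the largest rises and falls among called protein-coding genes with an average log2 CPM of at least 2 and no overlap between the libraries of the groups (8 each way for 30 nM against DMSO at either time, 5 each way for the other CDK-TCIP1 comparisons, 3 each way for Neg1 and Neg2 against DMSO). It added the 2 called members of each gene list with the largest rise and the 2 with the largest fall at 30 nM and 4 h. It also added BCL6, CDK9, CCNT1, HEXIM1, MYC, MCL1, BCL2L11, PMAIP1, BBC3, BMF, BCL2, FOXO3, CDKN1A, CDKN1B, PRDM1, CD69 and FAS whatever their values. The results of 2 genes that the rule named are not reported here.

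The 26 gene lists were written from general knowledge. They covered BCL6 targets, the pro-apoptotic BCL2 family, anti-apoptotic genes, death receptors and caspases, p53 targets, forkhead factors with CDK inhibitors, MYC targets, immediate early genes, P-TEFb with elongation factors, transcriptional cyclin-dependent kinases, replication-dependent histones, germinal centre B cell genes, the B cell receptor pathway, plasma cell genes, NF-kB targets, interferon-stimulated genes, G1/S with DNA replication, G2/M, heat shock, the unfolded protein and integrated stress response, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, and markers of T and NK cells, myeloid cells, erythroid cells, and epithelial cells with fibroblasts. Each list was tested with camera (limma 3.58.1), two-sided, with the correlation between its genes estimated from the data and Benjamini-Hochberg adjustment over the 24 lists with enough genes. A preset correlation of 0.01 was an alternative.

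The alternatives were DESeq2 1.42.0, the size factors of DESeq2 in edgeR, no filter on low counts, a fit of only the groups compared, the replicate number as a block, counts scaled from TPM by average transcript length, and leaving out each library in turn. After the data were seen, a fit without the 100 nM 2 h replicate 1 and Neg2 2 h replicate 1 libraries, and scaling by library size alone, were added. The steps were tested on simulated counts with 200 genes changed by known folds. For CDK-TCIP1 at 30 nM and 4 h against DMSO, 52.5% of the 2-fold changes were recovered among 17017 genes, and 89.1% of those at an average log2 CPM of at least 2, with 4 false calls. For Neg1 at 4 h against DMSO, 58.6% were recovered among 17011 genes, and 96.7% at that level, with 3 false calls. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.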

Results

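Poly(A) RNA of SUDHL5 cells, a human diffuse large B-cell lymphoma line of germinal centre type, was sequenced in 23 libraries after 2 or 4 h of treatment. CDK-TCIP1 is a bivalent molecule that links a ligand of the BTB domain of BCL6, the repressor that maintains germinal centre B cells, to a kinase inhibitor that binds CDK9, the kinase of the elongation factor P-TEFb. The series title describes borrowing a transcriptional kinase to activate apoptosis, and the libraries ask which mRNAs changed when cells received this molecule. It was given at 10 nM (2 libraries), 30 nM (4 libraries) and 100 nM (3 libraries) for 2 h and at 30 nM for 4 h (3 libraries). The comparison compounds Neg1 and Neg2, whose chemical difference from CDK-TCIP1 the labels do not give, had 2 libraries each at 30 nM for 2 h and for 4 h. DMSO had 3 libraries at 4 h. Library totals ran from 17396484 to 26373153 estimated counts.

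CDK-TCIP1 at 30 nM for 4 h changed 6531 of 17743 genes against DMSO of the same time, 3115 higher and 3416 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, n = 3 libraries in each group). The genes named next had the largest called changes among protein-coding genes with an average log2 CPM of at least 2 and no overlap between the groups. ADAMTSL4, an extracellular matrix protein, rose from 0.717 ± 0.297 to 17.02 ± 2.52 CPM (mean ± SD), a log2 fold change of 4.58 ± 0.34 (± SE). APOLD1 rose by 4.56 ± 0.24, the homeodomain factor PKNOX2 by 4.09 ± 0.36, the adhesion receptor ADGRF1 by 3.58 ± 0.34, the elongation scaffold AFF1 by 3.40 ± 0.23, the germ cell gene GCNA by 3.31 ± 0.17, the lactase gene LCT by 3.31 ± 0.29 and TNFRSF10D, a decoy receptor for TRAIL, by 3.02 ± 0.14. The glycosyltransferase gene B3GNT6 fell from 20.3 ± 0.641 to 3.64 ± 1.14 CPM, a log2 fold change of -2.48 ± 0.15. SCIMP, an immune membrane adaptor, fell by 2.39 ± 0.22 on this scale, HEATR3 by 2.30 ± 0.10, FNDC1 by 2.20 ± 0.12, the macrophage gene MPEG1 by 2.18 ± 0.20, PRIMA1 by 2.14 ± 0.18, the germinal centre serpin SERPINA9 by 2.11 ± 0.08 and the kinase SGK1 by 2.03 ± 0.10. Of the called genes, 991 were at least 2-fold higher and 521 at least 2-fold lower. In counts scaled by transcript length 4149 of the called genes (63.5%) were called again, 11 of them with the opposite sign. Among 10086 genes with an average log2 CPM of at least 2, 78.0% had a change within 0.5 on the log2 scale.

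On GRCh38, with GENCODE 29 gene bounds, ADAMTSL4 (ENSG00000143382) lies on chromosome 1 at 150549369 to 150560937 and AFF1 (ENSG00000172493) on chromosome 4 at 86935002 to 87141054. PKNOX2 (ENSG00000165495) lies on chromosome 11 at 125164687 to 125433389, and B3GNT6 (ENSG00000198488) on the same chromosome at 77034398 to 77041973. BCL6 (ENSG00000113916) spans 187721377 to 187745727 of chromosome 3, CDK9 (ENSG00000136807) 127785679 to 127790787 of chromosome 9 and MYC (ENSG00000136997) 127735434 to 127741434 of chromosome 8. SERPINA9 (ENSG00000170054) spans 94462717 to 94479689 of chromosome 14. Estimated counts are whole-transcript values, so no exon or untranslated region is singled out.

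**Figure D1:**
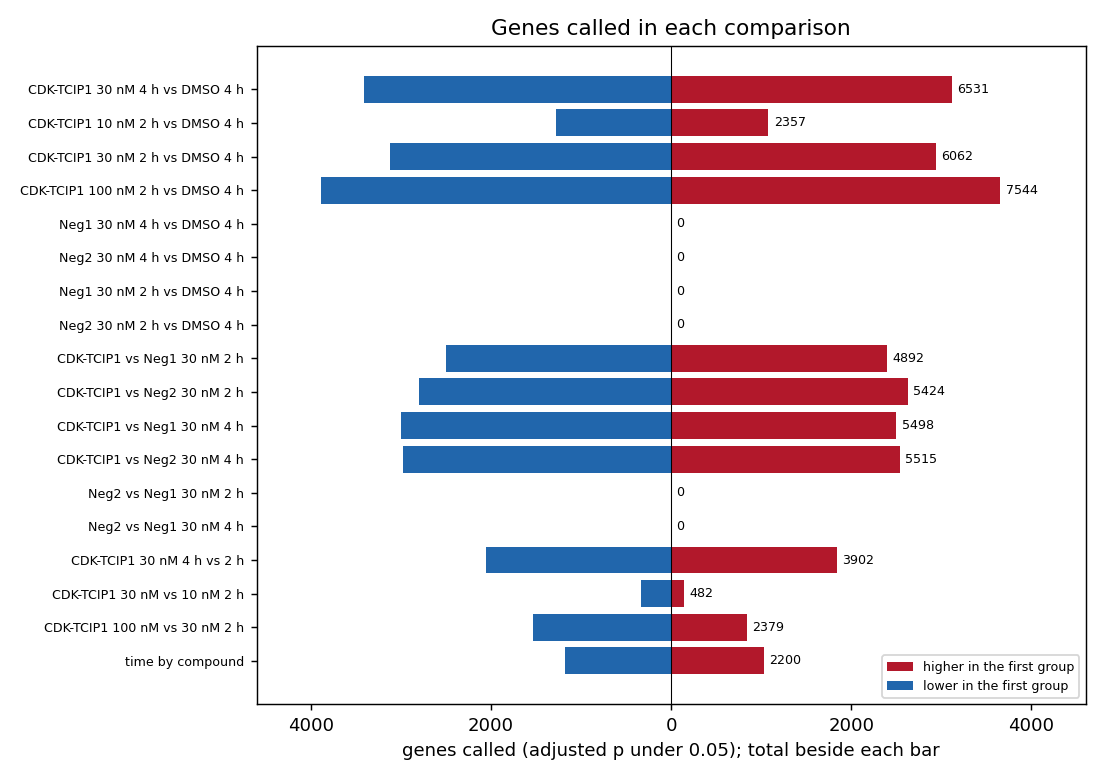
Number of genes called in each comparison (edgeR quasi-likelihood test, adjusted p under 0.05), with genes higher in the first group drawn to the right in red and genes lower drawn to the left in blue; the total stands beside each bar. Counts with CDK-TCIP1 against DMSO run from 2357 at 10 nM for 2 h to 7544 at 100 nM for 2 h, and no gene is called for Neg1 or Neg2 against DMSO or against each other.

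Genes of the p53 pathway rose at 4 h. Of 25 tested p53 targets, 17 rose and 2 fell (17 and 3 adjusted over the list alone), and the list stood above other genes (camera, adjusted p = 0.000718 with an estimated correlation). ZMAT3, an RNA-binding p53 target, rose by 1.39 ± 0.06 on the log2 scale, TNFRSF10B, a death receptor for TRAIL, by 1.38 ± 0.07, BBC3, which encodes the BH3-only protein PUMA, by 1.24 ± 0.13, FAS by 1.12 ± 0.14 and CDKN1A, the CDK inhibitor p21, by 0.42 ± 0.11. BBC3 went from 14.3 ± 1.35 to 33.8 ± 3.25 CPM and FAS from 9.88 ± 0.247 to 21.5 ± 1.78 CPM. The members that fell were the antiproliferative gene BTG2 (-0.39 ± 0.08) and RRM2B (-0.17 ± 0.05). The call of RRM2B was lost without the 4 h replicate 2 (adjusted p = 0.057, edgeR), and its change was 0.04 in counts scaled by transcript length. FAS overlaps ACTA2 on the opposite strand, and reads of the overlap cannot be assigned with certainty.

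Apoptosis genes moved in both directions. In the pro-apoptotic BCL2 family 4 of 13 members rose and 2 fell (the same counts adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). BBC3, PMAIP1, which encodes NOXA, at 0.64 ± 0.07, and BCL2L11, which encodes BIM, at 0.42 ± 0.06 rose, whereas BMF (-0.65 ± 0.14) and BAK1 (-0.23 ± 0.08) fell. Among 11 anti-apoptotic genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation). The inhibitor of apoptosis BIRC2 rose by 0.56 ± 0.06 and MCL1 by 0.34 ± 0.05, while BIRC6 fell by 0.46 ± 0.06 and BIRC3 by 0.44 ± 0.07, and BCL2, at 3.41 ± 0.367 CPM in DMSO, had a change of -0.14 ± 0.25 that did not pass the test. Of 19 death receptors and caspases 3 rose and 10 fell (4 and 10 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). TNFRSF10B and FAS rose, and the apoptosome genes APAF1 (-0.93 ± 0.09) and CASP9 (-0.87 ± 0.15) fell. The call of BAK1 was lost without DMSO replicate 1, 4 h replicate 1 or 4 h replicate 3 (adjusted p of 0.074, 0.104 and 0.118, edgeR).

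BCL6 mRNA fell from 401 ± 8.47 to 342 ± 9.02 CPM, a log2 fold change of -0.23 ± 0.05 (adjusted p = 0.000219, edgeR). Of 35 tested genes described as repressed by BCL6, 10 rose, 6 fell and 19 did not pass the test (11 and 6 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation). CDKN1B, the CDK inhibitor p27, rose by 1.57 ± 0.08, from 34.1 ± 5.02 to 101 ± 6.51 CPM, and the activation marker CD69 rose by 0.84 ± 0.11. NOTCH2 (-0.90 ± 0.15) and BMF fell. PRDM1, the plasma cell factor BLIMP1, was at 0.282 ± 0.114 CPM in DMSO and 0.865 ± 0.359 CPM after CDK-TCIP1, a change of 1.58 ± 0.73 that did not pass the test (adjusted p = 0.087, edgeR), although it did when only the 6 libraries compared were fitted (adjusted p = 0.0401). Of 17 forkhead factors and CDK inhibitors 6 rose and 2 fell (7 and 2 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). They included CDKN1B, FOXO3 (0.57 ± 0.12) and the stress gene GADD45A (0.63 ± 0.13), against FOXO4 (-0.69 ± 0.20) and CCNG2 (-0.57 ± 0.06).

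Components of the elongation machinery moved apart. Among 25 genes of P-TEFb and the elongation factors 9 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.493 with an estimated correlation). AFF1, from 1.92 ± 0.285 to 20.4 ± 0.662 CPM, CDK9 (0.69 ± 0.08) and its cyclin CCNT1 (0.85 ± 0.07) rose. The P-TEFb inhibitor HEXIM1 fell from 25.6 ± 0.633 to 10.9 ± 0.141 CPM (-1.23 ± 0.13), and MEPCE, the capping enzyme of 7SK RNA, fell by 1.54 ± 0.08. ELL2 fell by 1.51 ± 0.47, but its call was lost without the 4 h replicate 1 (-1.08, adjusted p = 0.0796, edgeR) and with length scaling (-0.10, adjusted p = 0.952). Of 16 transcriptional cyclin-dependent kinases and partners 6 rose and 5 fell (7 and 5 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation), with rises of the splicing-linked cyclins CCNL2 (1.23 ± 0.07) and CCNL1 (0.88 ± 0.08) and falls of POLR2A, the largest subunit of RNA polymerase II (-1.28 ± 0.07), and of the Mediator cyclin CCNC (-0.53 ± 0.10).

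Germinal centre genes fell. Of 25 tested, 18 fell and 2 rose (19 and 2 adjusted over the list alone), and the list stood below other genes (camera, adjusted p = 0.000718 with an estimated correlation). SERPINA9 went from 155 ± 4.97 to 35.9 ± 5.97 CPM, and KLHL14 changed by -1.81 ± 0.43. The members that rose were CD38, an ectoenzyme also high in plasma cells (1.32 ± 0.17), and the transcription factor MYBL1 (0.56 ± 0.05). Of 19 genes of the B cell receptor pathway 4 rose and 8 fell (4 and 8 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). The adaptor BLNK fell by 1.21 ± 0.07 and MALT1 by 0.78 ± 0.06, and BCL10 (0.65 ± 0.08) and PLCG2 (0.38 ± 0.05) rose. In the plasma cell list 1 of 12 genes rose and 4 fell (1 and 5 adjusted over the list alone; adjusted p = 0.493 with an estimated correlation). The chaperone HSP90B1 rose by 0.46 ± 0.05 and CD27 fell by 1.16 ± 0.07. Of 21 NF-kB targets 2 rose and 8 fell (2 and 8 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), LTA by -1.36 ± 0.21 and CD83 by -1.16 ± 0.12. The 2 called rises of that list were not firm. NFKBIZ (0.34 ± 0.13) lost its call in most fits without 1 of the 6 libraries, with no filter (adjusted p = 0.186, edgeR), with only the groups compared (0.0546) and with length scaling, where it was at -0.02, and CCR7 (3.56 ± 1.39) lay at 0.248 ± 0.121 CPM and lost its call without DMSO replicate 3 (adjusted p = 0.121, edgeR) and with no filter (0.0814). Both also lost it without the 2 libraries 100 nM replicate 1 and Neg2 2 h replicate 1 (adjusted p of 0.0548 and 0.0579, edgeR), an alternative chosen after seeing the data. Of 30 interferon-stimulated genes 3 rose and 8 fell (3 and 8 adjusted over the list alone; adjusted p = 0.551 with an estimated correlation), with TRIM22 at 0.87 ± 0.08 and USP18 at -1.07 ± 0.23. OASL (-1.17 ± 0.38) lost its call without DMSO replicate 2 or 4 h replicate 2 (adjusted p of 0.133 and 0.0696, edgeR).

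**Figure D2:**
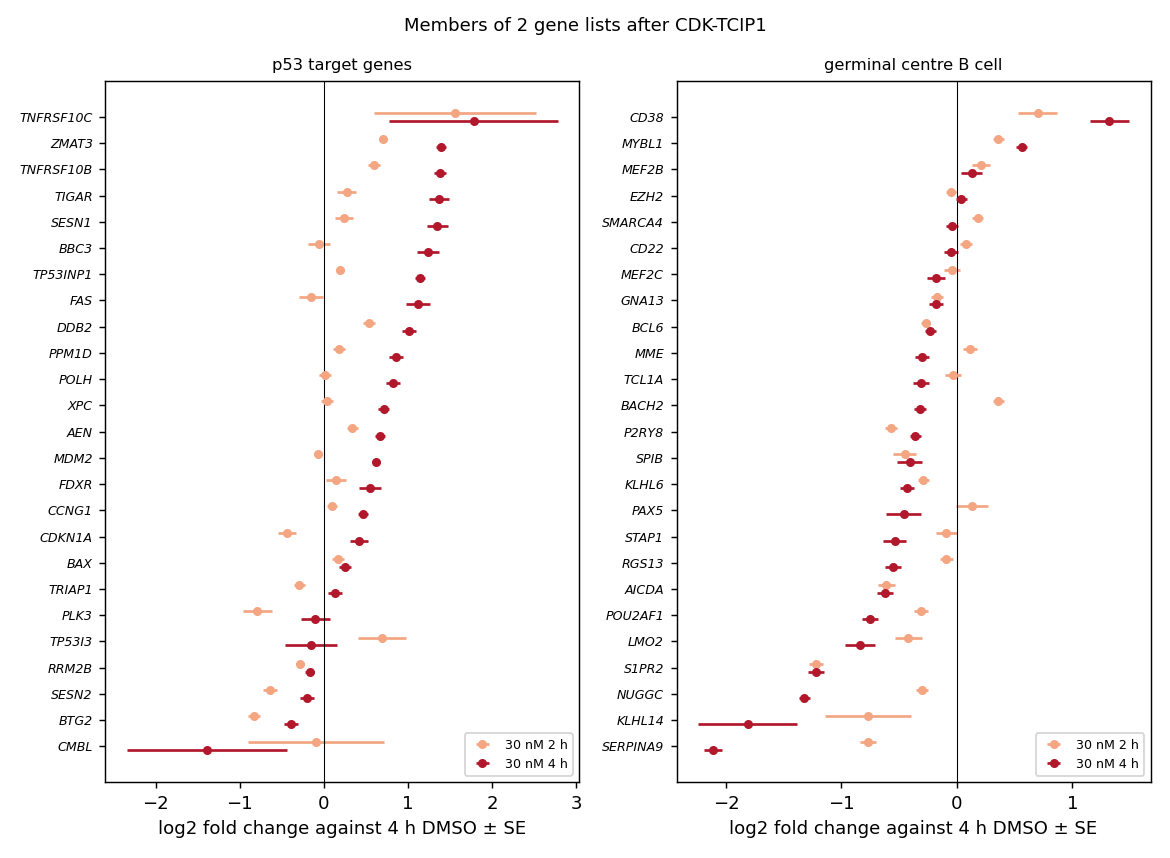
Log2 fold change (± SE) against the 4 h DMSO libraries for each tested member of the p53 target list (left) and the germinal centre list (right) after CDK-TCIP1 at 30 nM for 2 h (pale) and 4 h (dark). At 4 h 17 of 25 p53 targets rose and 2 fell, and 18 of 25 germinal centre genes fell and 2 rose; at 2 h 6 p53 targets rose and 6 fell, and 11 germinal centre genes fell and 4 rose.

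MYC fell from 139 ± 4.15 to 59.5 ± 3.37 CPM (-1.22 ± 0.09, adjusted p = 1.13e-11, edgeR). Of 33 MYC targets 19 fell and none rose (21 and 0 adjusted over the list alone). Camera gave an adjusted p = 0.25 with an estimated correlation. Among those that fell were PUS7 (-0.92 ± 0.10) and the ribosome biogenesis gene UTP20 (-0.82 ± 0.08). Of 26 immediate early genes 12 fell and 3 rose (13 and 3 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). MYC fell and IER5 rose by 0.36 ± 0.08, whereas the fall of FOSB (-1.20 ± 0.36) was lost without DMSO replicate 1 or 4 h replicate 1 (adjusted p of 0.0545 and 0.0533, edgeR) and with length scaling (-0.76, adjusted p = 0.191). Among 26 G2/M genes 16 fell and 3 rose (17 and 4 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), with HMMR at -0.76 ± 0.08 and DLGAP5 at -0.61 ± 0.06 against the kinesin KIF23 at 0.29 ± 0.07 and the kinase BUB1 at 0.23 ± 0.06. Among 24 genes of G1/S and DNA replication 7 rose and 6 fell (7 and 6 adjusted over the list alone; adjusted p = 0.711 with an estimated correlation). CDT1 rose by 0.39 ± 0.06 and CDC45 by 0.29 ± 0.05, while the ribonucleotide reductase gene RRM2 fell by 1.51 ± 0.28 and CCNE2 by 0.58 ± 0.08.

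Many stress genes were lower, but neither list passed camera with an estimated correlation. Of 12 heat shock genes 10 fell and none rose (10 and 0 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation), and HSPA1B (-1.11 ± 0.17) and HSPA1A (-0.84 ± 0.22) are near-identical copies whose separate values are uncertain. Of 17 genes of the unfolded protein and integrated stress response 10 fell and none rose (11 and 0 adjusted over the list alone; adjusted p = 0.19 with an estimated correlation). DDIT3, the stress factor CHOP, fell by 1.40 ± 0.12 and VLDLR by 1.16 ± 0.07. Conversely, 37 of 41 cytosolic ribosomal protein genes rose and none fell (37 and 0 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation), RPLP2 by 0.39 ± 0.08 and RPS15 by 0.37 ± 0.08. Of 13 mitochondrially encoded mRNAs 10 rose and none fell (11 and 0 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). MT-CO3 rose by 0.34 ± 0.07, and MT-ND3 (0.58 ± 0.20) lost its call without most single libraries, with no filter (adjusted p = 0.0866, edgeR) and with only the groups compared (0.0618). These mRNAs took 5.88 to 6.23% of the counts in the CDK-TCIP1 libraries and 4.79 to 5.32% in DMSO. As values are relative, a gain of ribosomal protein and mitochondrial mRNAs cannot be told from a loss of the others. Of 31 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, 5 rose and none fell (5 and 0 adjusted over the list alone; adjusted p = 0.25 with an estimated correlation). H2BC5 rose by 1.59 ± 0.32, and H2BC6 (4.16 ± 1.29, at 0.644 ± 0.496 CPM) lost its call without DMSO replicate 2 (adjusted p = 0.0505, edgeR).

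Markers of other cell types gave few calls. In the list for T and NK cells 1 of 5 genes fell and none rose (1 and 0 adjusted over the list alone; adjusted p = 0.6 with an estimated correlation), namely the kinase LCK, at 47.6 ± 0.649 CPM in DMSO (-0.42 ± 0.08). Neither of the 2 myeloid genes was called, over all genes or adjusted over the list alone. Of 2 erythroid genes 1 rose (1 higher and 1 lower adjusted over the list alone), the haem synthesis gene ALAS2, from 0.0806 ± 0.107 to 1.03 ± 0.79 CPM, a call lost with length scaling (2.77 from 3.62, adjusted p = 0.0615, edgeR). Of 7 epithelial and fibroblast markers 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.675 with an estimated correlation). ACTA2, smooth muscle actin, rose from 0.743 ± 0.23 to 7.44 ± 0.929 CPM, and decorin, DCN, fell by 0.42 ± 0.08 from 47.0 ± 1.63 CPM. With a preset correlation of 0.01 in place of the estimated one, 10 lists passed the test at 4 h instead of 2. IFI27, CCNC and KIF23, called in the counts as summed, lost their calls with length scaling (adjusted p of 0.0627, 0.189 and 0.0558, edgeR). IFI27 went from 2.25 to 1.92, KIF23 from 0.29 to 0.27 and CCNC from -0.53 to -0.23.

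Against the comparison compounds at 30 nM and 4 h, CDK-TCIP1 raised many of the genes named above. ADAMTSL4 was higher than with Neg1 by 4.96 ± 0.42 on the log2 scale and than with Neg2 by 4.68 ± 0.40 (n = 3 and 2 libraries), PKNOX2 by 4.43 ± 0.46 and 4.13 ± 0.43, APOLD1 by 4.11 ± 0.28 and 3.69 ± 0.27, and AFF1 by 3.44 ± 0.28 and 3.33 ± 0.27. GCNA was higher than with Neg1 by 3.34 ± 0.20 and LCT than with Neg2 by 3.63 ± 0.35. B3GNT6 was lower by -2.66 ± 0.16 and -2.63 ± 0.16, MPEG1 by -2.14 ± 0.22 and -2.37 ± 0.21 and PRIMA1 by -2.28 ± 0.20 and -2.21 ± 0.19. SCIMP (-2.34 ± 0.24) and FNDC1 (-2.21 ± 0.12) were lower than with Neg1, and HEATR3 (-2.21 ± 0.10) and SERPINA9 (-2.15 ± 0.08) than with Neg2. The p53 targets were again higher (17 higher and 2 lower of 25 against Neg1, 15 and 2 against Neg2; 18 and 2, and 17 and 3, adjusted over the list alone), with camera adjusted p of 0.000787 and 0.00132 and an estimated correlation. Germinal centre genes were lower (17 lower and 2 higher of 25 against Neg1, 16 and 2 against Neg2; 19 and 2, and 16 and 2, adjusted over the list alone; adjusted p of 0.000787 and 0.00132). The edgeR test called 5498 genes against Neg1 (2501 higher, 2997 lower) and 5515 against Neg2 (2539 higher, 2976 lower). The count against Neg1 was 3618 without Neg1 4 h replicate 2, and with length scaling the counts were 3420 and 3386.

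For Neg1 and Neg2 themselves no gene passed the test against DMSO at 4 h. The edgeR quasi-likelihood test called 0 genes for each, with 735 genes at an unadjusted p under 0.05 for Neg1 and 1011 for Neg2, where chance gives 887, and DESeq2 called 1 and 0. Of 10086 genes with an average log2 CPM of at least 2, the 95% interval of the difference from DMSO lay within 2-fold for 9903 with Neg1 (98.2%) and 9905 with Neg2 (98.2%). The G1/S and DNA replication list was slightly lower with either compound, with median log2 fold changes of -0.08 (camera, adjusted p = 0.0053) and -0.06 (adjusted p = 0.0437), although none of its 24 genes was called (1 and 0 lower adjusted over the list alone). Both values rest on the same 3 DMSO libraries and are not independent. The transcriptional kinase list was lower with Neg2 (median -0.11, adjusted p = 0.0437), with no gene called over all genes and 1 lower adjusted over the list alone. With the preset correlation 4 lists passed for Neg1 and 5 for Neg2. The counts of 0 became 6 for Neg1 and 54 for Neg2 when only the libraries compared were fitted, and 4 and 15 with no filter on low counts.

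At 2 h against the 4 h DMSO libraries, no gene was called by edgeR for Neg1 or Neg2 either (820 and 1130 at an unadjusted p under 0.05; DESeq2 called 3 and 1). The counts were 9 and 26 with no filter and 10 and 1 with only the groups compared. The 95% interval lay within 2-fold for 9896 and 9879 of the 10086 genes. Neg2 and Neg1 were compared directly at the matched dose. At 2 h edgeR called 0 genes (1090 at an unadjusted p under 0.05, DESeq2 1; 24 with no filter, 11 with only the groups compared), and the interval of the difference lay within 2-fold for 9799 of the 10086 genes (97.2%). At 4 h edgeR called 0 genes (435 at an unadjusted p under 0.05, DESeq2 1; 2 with no filter, 12 with only the groups compared), and the interval lay within 2-fold for 9870 genes (97.9%). No gene list passed camera with an estimated correlation in these direct comparisons or at 2 h against DMSO. With the preset one 3 and 1 lists passed for Neg2 against Neg1 at 2 h and 4 h, and 0 and 1 for Neg1 and Neg2 at 2 h against DMSO. Without Neg2 2 h replicate 2, which left a single library whose spread was taken from the other groups, 93 genes were called against DMSO and 89 against Neg1.

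**Figure D3:**
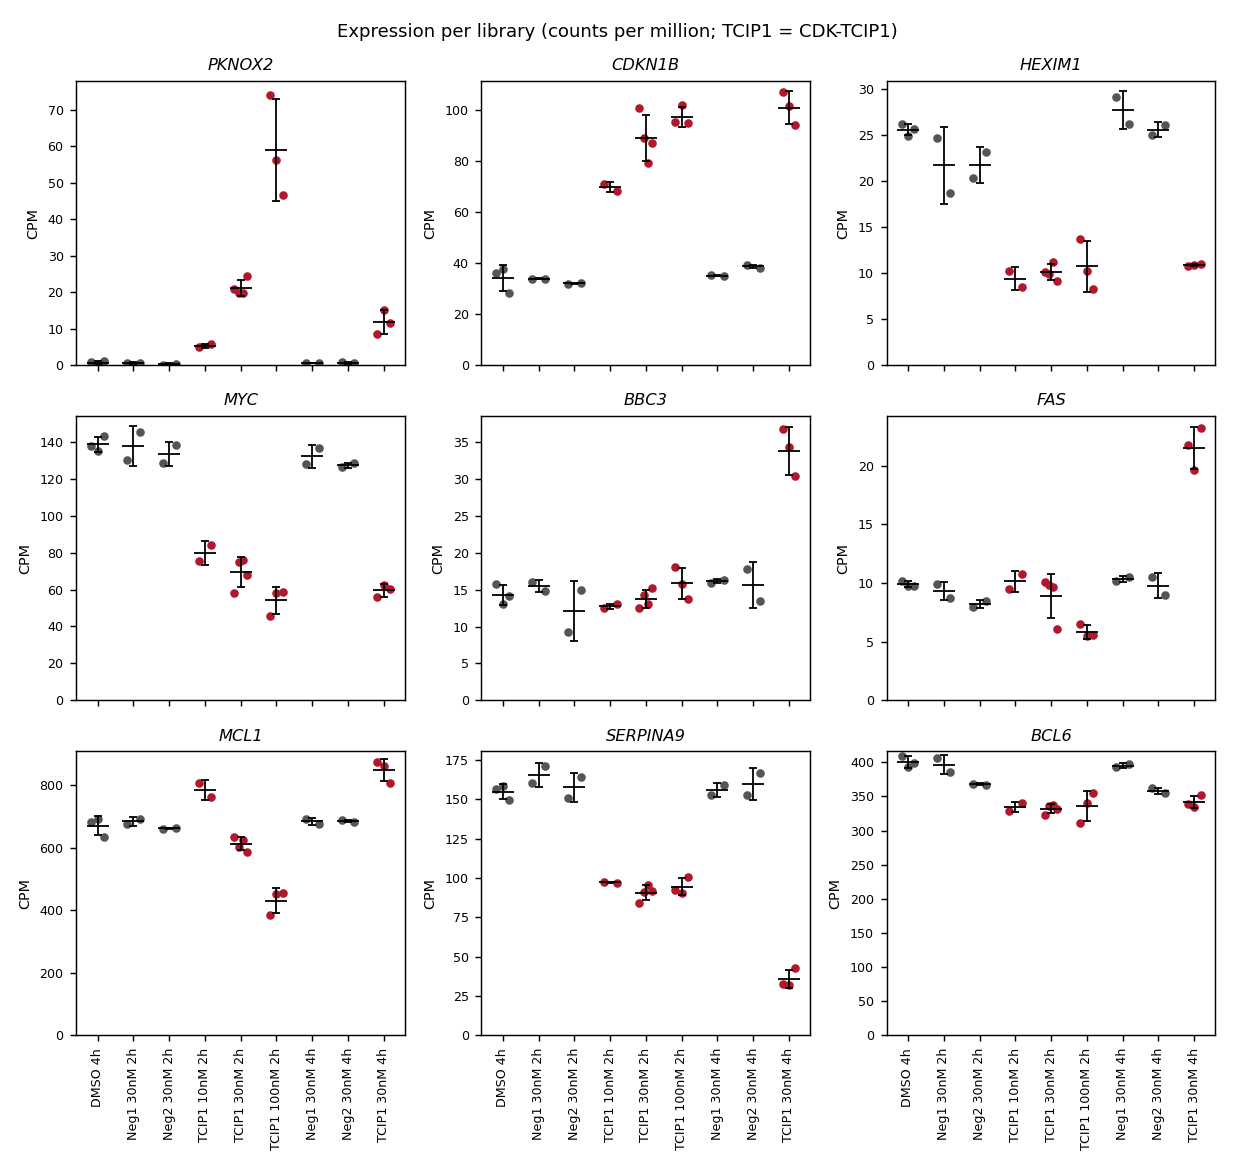
CPM of 9 named genes in each library (points), by group along the horizontal axis, with the group mean and SD (black); CDK-TCIP1 groups are red and DMSO, Neg1 and Neg2 groups are grey. PKNOX2 rises with the dose at 2 h from 5.31 to 59.0 CPM, BBC3 and FAS are called higher than DMSO at 4 h and at none of the 2 h doses, and MCL1 is above DMSO at 10 nM and below it at 100 nM.

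After 2 h at 30 nM (4 libraries) several genes named by the same limits against DMSO (3 libraries) had also been named at 4 h. PKNOX2 rose by 4.94 ± 0.34 on the log2 scale, ADGRF1 by 4.09 ± 0.33, APOLD1 by 4.05 ± 0.24, ADAMTSL4 by 3.68 ± 0.33, the complement protease MASP2 by 3.31 ± 0.23, PEX5L by 3.21 ± 0.27, LCT by 2.94 ± 0.28 and GCNA by 2.89 ± 0.17. CNNM4 fell by 2.01 ± 0.20, SGK1 by 1.87 ± 0.09, B3GNT6 by 1.87 ± 0.13, TNFRSF1B, a receptor for TNF, by 1.86 ± 0.17, ZNF248 by 1.84 ± 0.20, ZNF324B by 1.82 ± 0.27 and the Wnt receptor FZD5 by 1.78 ± 0.24. In all 6062 genes were called, 2939 higher and 3123 lower (48.5% higher; 36.8% with scaling by library size alone), and 4035 with length scaling. The rise of PEX5L was 1.08 with length scaling and no longer called (adjusted p = 0.153, edgeR), and the comparison joins 2 h of treatment with 4 h of vehicle.

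Of the apoptosis and BCL6 genes, CDKN1B (1.39 ± 0.08), CD69 (1.25 ± 0.10), PMAIP1 (0.64 ± 0.07), CCNT1 (0.61 ± 0.06) and CDK9 (0.45 ± 0.08) rose by 2 h, and HEXIM1 (-1.34 ± 0.12), MYC (to 69.2 ± 8.11 CPM), BMF (-0.72 ± 0.13), CDKN1A (-0.44 ± 0.11) and BCL6 (-0.27 ± 0.04) fell. MCL1 changed by -0.13 ± 0.05, a call lost without most single libraries. With length scaling the calls of CDK9 (0.31), BMF (-0.26) and CDKN1A (-0.15) were lost (adjusted p of 0.0887, 0.507 and 0.537, edgeR). BBC3 (-0.06 ± 0.13), FAS (-0.15 ± 0.14), BCL2L11 (0.05 ± 0.06), FOXO3 (-0.21 ± 0.12), BCL2 (-0.45 ± 0.24) and PRDM1 (0.66 ± 0.70) did not pass the test, and BCL2L11 was at -0.02 with scaling by library size alone. BCL2 passed without 30 nM 2 h replicate 2 (-0.64, adjusted p = 0.0462, edgeR). No list passed camera with an estimated correlation (smallest adjusted p = 0.171), and 9 did with the preset correlation. Of 25 p53 targets 6 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.649 with an estimated correlation), of 35 BCL6 targets 6 rose and 10 fell (6 and 11 adjusted over the list alone; 0.734), and of 25 germinal centre genes 4 rose and 11 fell (5 and 11 adjusted over the list alone; 0.188). Of 17 genes of the unfolded protein and integrated stress response 11 fell and none rose (11 and 0 adjusted over the list alone; adjusted p = 0.171 with an estimated correlation). Of 26 G2/M genes 17 fell and none rose (17 and 0 adjusted over the list alone; 0.238), of 26 immediate early genes 13 fell and 1 rose (13 and 2 adjusted over the list alone; 0.317), and of 41 ribosomal protein genes 40 rose (40 adjusted over the list alone; 0.32).

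With the matched 2 h libraries of Neg1 and Neg2 in place of DMSO, some of the named genes were the same. PKNOX2 was higher by 5.24 ± 0.43 against Neg1 and 6.61 ± 0.50 against Neg2 (n = 4 and 2 libraries), ADAMTSL4 by 3.67 ± 0.40 and 4.34 ± 0.42, and ADGRF1 by 3.36 ± 0.36 and 3.78 ± 0.38. Against Neg1, PEX5L (3.24 ± 0.32) and APOLD1 (3.10 ± 0.26) were higher and B3GNT6 (-1.89 ± 0.14) and KLHL25 (-1.89 ± 0.15) were lower, and against Neg2, CCDC17 (3.33 ± 0.28) was higher and MPEG1 (-2.00 ± 0.19) lower. SGK1 was lower by -1.90 ± 0.09 and -1.95 ± 0.09, and ZNF248 by -1.92 ± 0.22 and -1.99 ± 0.22. With length scaling the calls of PEX5L and ZNF248 were lost (1.08 and -0.56 against Neg1, adjusted p of 0.26 and 0.355; -0.71 for ZNF248 against Neg2, adjusted p = 0.204; edgeR). The calls of UTP14C (7.07 ± 2.12) and of the read-through gene ARPIN-AP3S2 (-2.51 ± 0.91) against Neg2 share reads with overlapping genes and were lost without either Neg2 library (adjusted p of 0.117 and 0.138 for UTP14C, 0.168 and 0.128 for ARPIN-AP3S2, edgeR). That of ARPIN-AP3S2 was also lost with DESeq2 (adjusted p = 0.149), with its size factors (0.0502), with no filter (0.0971), with length scaling (0.0711), with only the groups compared (0.123) and without 30 nM replicate 1, 2 or 3 (0.0666, 0.0969 and 0.0823).

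The edgeR test called 4892 genes against Neg1 at 2 h (48.9% higher; 30.9% with library size alone) and 5424 against Neg2 (48.4% higher; 37.1% with library size alone), and 2861 and 3351 with length scaling. Leaving out Neg1 2 h replicate 1 or 2 gave 3106 or 3074 genes, and leaving out Neg2 2 h replicate 1, which lay apart at -17.4 on the third principal component against 0.6 for replicate 2, gave 3286. No list passed camera with an estimated correlation (smallest adjusted p of 0.085 and 0.0793). Genes of the unfolded protein and integrated stress response came closest, with 12 of 17 lower against Neg1 and 11 against Neg2 (14 lower, and 11 lower and 1 higher, adjusted over the list alone).

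Dose was compared at 2 h. At 10 nM 2357 genes were called against DMSO (1078 higher, 1279 lower; n = 2 and 3 libraries), and at 100 nM 7544 (3652 higher, 3892 lower; n = 3 and 3 libraries; 48.4% higher, 30.6% with library size alone). PKNOX2 went from 0.689 ± 0.387 CPM in DMSO to 5.31 ± 0.548 at 10 nM, 21.2 ± 2.17 at 30 nM and 59.0 ± 14 at 100 nM. At 100 nM PKNOX2 rose by 6.42 ± 0.34, ADGRF1 by 5.55 ± 0.34, ADAMTSL4 by 3.97 ± 0.34, APOLD1 by 3.96 ± 0.25 and MASP2 by 3.57 ± 0.24, and EFNA4 (-2.96 ± 0.27), TEF (-2.57 ± 0.19), DDIT3 (-2.56 ± 0.14) and SGK1 (-2.47 ± 0.10) fell. The count at 10 nM was 1041 without its replicate 1, 1258 without its replicate 2 and 990 with length scaling. Scaling by library size alone moved the median of all genes at 100 nM from 0.02 to -0.14 on the log2 scale, so changes there are relative to the bulk of genes.

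The fixed genes followed dose in different ways. CDKN1B rose at 10 nM (1.03 ± 0.09) and at 100 nM (1.51 ± 0.08), and MYC fell by 0.79 ± 0.10 and 1.35 ± 0.09. HEXIM1 fell by 1.45 ± 0.15 and 1.25 ± 0.13, BCL6 by 0.26 ± 0.05 and 0.26 ± 0.05, and CD69 (1.54 ± 0.12 and 0.97 ± 0.11), PMAIP1 (0.62 ± 0.08 and 0.45 ± 0.07) and CCNT1 (0.56 ± 0.07 and 0.41 ± 0.07) rose at either dose. MCL1 was higher at 10 nM (0.23 ± 0.06), where its call was lost without DMSO replicate 3, without 10 nM replicate 1 (adjusted p of 0.0747 and 0.182, edgeR) or with length scaling (0.13, adjusted p = 0.28), and lower at 100 nM (-0.64 ± 0.06, adjusted p = 1.99e-11). CDK9 rose at 10 nM (0.53 ± 0.09) and had a value of 0.04 ± 0.09 at 100 nM, which did not pass the test and was -0.12 with library size alone. FAS fell at 100 nM (-0.76 ± 0.16) and was at 0.04 ± 0.16 at 10 nM. BMF (-1.11 ± 0.15), FOXO3 (-0.50 ± 0.13), CDKN1A (-0.43 ± 0.12) and BCL2L11 (-0.17 ± 0.06) were lower at 100 nM. The call of CDKN1A there was lost with length scaling, at 0.14, and that of BCL2L11 without 100 nM replicate 1 (-0.07, adjusted p = 0.403, edgeR). BCL2L11 also lost it without DMSO replicate 1 or 2 (adjusted p of 0.0566 and 0.0689, edgeR), with length scaling (0.114), with only the groups compared (0.105) and without the 2 libraries named below (-0.09, adjusted p = 0.224). At 10 nM BMF (-0.42 ± 0.16), CDKN1A (-0.32 ± 0.13), FOXO3 (0.14 ± 0.14) and BCL2L11 (-0.01 ± 0.07) did not pass. BMF passed there without DMSO replicate 1 (-0.54, adjusted p = 0.0336, edgeR) and without the 2 libraries 100 nM replicate 1 and Neg2 2 h replicate 1 (-0.44, adjusted p = 0.0418), an alternative chosen after seeing the data. The call of BCL2 (-0.91 ± 0.30) was lost without either 10 nM library (adjusted p of 0.307 and 0.0964, edgeR), without DMSO replicate 1 or 2 (0.108 and 0.0655), with no filter (0.097) and with length scaling (0.202). BBC3 and PRDM1 passed at neither dose, with BBC3 at -0.17 ± 0.16 and 0.15 ± 0.14, the latter -0.01 with library size alone.

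No list passed camera with an estimated correlation at 10 nM or 100 nM (smallest adjusted p of 0.166 and 0.211), and 5 and 9 did with the preset one. At 100 nM 13 of 13 mitochondrially encoded mRNAs rose (13 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). None of them was called at 10 nM, over all genes or adjusted over the list alone. These mRNAs took 6.11 to 6.84% of the counts at 100 nM, 4.72 to 5.16% at 10 nM and 5.71 to 6.13% at 30 nM. Of 41 ribosomal protein genes 14 rose at 10 nM and 40 at 100 nM (24 and 40 adjusted over the list alone; adjusted p of 0.63 and 0.211). Genes of the unfolded protein and integrated stress response fell, 7 of 17 at 10 nM and 13 at 100 nM (9 and 13 adjusted over the list alone; adjusted p of 0.208 and 0.211), with a median of -0.92 at 100 nM. Of 35 BCL6 targets 4 rose and 4 fell at 10 nM and 5 rose and 15 fell at 100 nM (6 and 7, and 5 and 15, adjusted over the list alone; adjusted p of 0.907 and 0.474). Of 25 p53 targets 7 rose and 9 fell at 100 nM (7 and 9 adjusted over the list alone; adjusted p = 0.961), with a median of 0.04 that was -0.11 with library size alone. Of 19 B cell receptor genes 12 rose and 3 fell at 100 nM (12 and 3 adjusted over the list alone; adjusted p = 0.211).

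Between 10 and 30 nM, 482 genes differed (147 higher and 335 lower at 30 nM; 30.5% higher, 17.5% with library size alone). Length scaling gave 91, DESeq2 824, and the fit without 100 nM replicate 1 and Neg2 2 h replicate 1, chosen after seeing the data, 927. ADGRF1 was higher by 2.25 ± 0.32, PKNOX2 by 1.99 ± 0.30, PEX5L by 1.47 ± 0.27, ADAMTSL4 by 1.47 ± 0.31 and KIFBP by 1.39 ± 0.23, and BBS12 (-1.03 ± 0.24), SLC19A2 (-0.98 ± 0.26), KLHL25 (-0.91 ± 0.16) and VANGL1 (-0.82 ± 0.18) were lower. Of these, only ADGRF1 and PKNOX2 kept their calls without either 10 nM library or with length scaling, where VANGL1 was at 0.01. SLC19A2 also lost its call without 30 nM replicate 3 or 4 (adjusted p of 0.0514 and 0.115, edgeR). The count was 150 and 77 without 10 nM replicate 1 and 2, and 302 without 30 nM replicate 4. From 30 to 100 nM 2379 genes differed (843 higher, 1536 lower; 35.4% higher, 6.8% with library size alone; 837 with length scaling, 1456 with only the groups compared). PKNOX2 (1.48 ± 0.22), ADGRF1 (1.46 ± 0.23), RHBDL1 (1.11 ± 0.21) and KIFBP (0.99 ± 0.18) were higher, and ZSCAN26 (-1.68 ± 0.21), PLPP6 (-1.62 ± 0.27), EFNA4 (-1.52 ± 0.27) and KBTBD7 (-1.36 ± 0.25) were lower. KIFBP lost its call with length scaling (0.96, adjusted p = 0.181, edgeR), and CCDC78 (0.93 ± 0.24) did so with length scaling and without 100 nM replicate 1 (0.67 and 0.68, adjusted p of 0.168 and 0.142, edgeR). That library lay at -27.8 on the second principal component, against -13.5 and -13.3 for the others of its group, and the count of this step was 869 without it. Library size alone moved the median of all genes in this step from -0.01 to -0.10. Across the steps no list passed camera with an estimated correlation (smallest adjusted p of 0.157 and 0.226).

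Time was compared at 30 nM, where p53 targets were higher and germinal centre genes lower at 4 h than at 2 h (n = 3 and 4 libraries). AFF1 was higher at 4 h by 1.70 ± 0.19, BBC3 by 1.30 ± 0.12, INKA2 by 1.33 ± 0.22, ZBED6 by 1.32 ± 0.24 and ZNF324B by 1.32 ± 0.27. ZPBP2 (-1.35 ± 0.15), SERPINA9 (-1.34 ± 0.07), PRIMA1 (-1.19 ± 0.18), the protein kinase C gene PRKCH (-1.13 ± 0.17) and the calcium channel gene ITPR1 (-1.12 ± 0.13) were lower. Of 25 p53 targets 20 were higher and 1 lower (21 and 1 adjusted over the list alone; camera, adjusted p = 1.46e-05 with an estimated correlation), and of 25 germinal centre genes 11 were lower and 3 higher (14 and 3 adjusted over the list alone; adjusted p = 0.00422). Of 33 MYC targets 22 were lower and 3 higher (22 and 4 adjusted over the list alone; adjusted p = 0.192 with an estimated correlation). The edgeR test called 3902 genes, 1841 higher and 2061 lower (47.2% higher; 61.2% with library size alone), and 1887 with length scaling. INKA2 and PRKCH lost their calls with length scaling (0.60 and -0.49, adjusted p of 0.561 and 0.204, edgeR).

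The difference over time was also tested against the matched compounds, as the change of CDK-TCIP1 from the mean of Neg1 and Neg2 at 4 h minus that at 2 h. BBC3 (1.09), FAS (1.07), ZMAT3 (0.81) and FOXO3 (0.80) had called positive differences on the log2 scale, and SERPINA9 (-1.30) and PRIMA1 (-1.23) called negative ones. The test called 2200 genes, 1026 positive and 1174 negative (46.6% positive; 60.3% with library size alone), and 642 with length scaling, 584 of them shared. Of 25 p53 targets 19 were positive and none negative (19 and 0 adjusted over the list alone; camera, adjusted p = 2.47e-05 with an estimated correlation), and of 25 germinal centre genes 11 were negative and 1 positive (11 and 3 adjusted over the list alone; adjusted p = 0.0097).

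The effects of CDK-TCIP1 at different doses and times were correlated across 10086 genes, which are not independent replicates and which shared the DMSO libraries. Between 2 h and 4 h at 30 nM Pearson's r was 0.814, where simulated groups without an effect gave 0.548, and the covariance was 0.186 against a simulated 0.0127. Genes called in both numbered 1987 higher, 2031 lower and 90 in opposite directions, where independent lists would share 516 and 601. Between 10 and 30 nM r was 0.882 (simulated 0.494; covariance 0.136 against 0.0127), with 988 genes higher and 1204 lower in both against 179 and 225 for independent lists. Between 30 and 100 nM r was 0.916 (simulated 0.546; covariance 0.256 against 0.0127), with 2470 higher and 2731 lower in both against 605 and 685. Effects of CDK-TCIP1 at 4 h had r of 0.132 with those of Neg1 and 0.186 with those of Neg2 (simulated 0.452 and 0.456). Covariances were 0.0131 and 0.0158 against 0.0124 and 0.0122. The simulated groups had no effect, and large effects of CDK-TCIP1 alone lower r, so these r cannot be set against the simulated ones. Neg1 and Neg2 at 4 h had r of 0.665 with each other (simulated 0.404; covariance 0.0227 against 0.0122). The 3 DMSO libraries could not be split into parts of 2, so part of each excess can come from the shared controls.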

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

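Of the tests in this part, those of time in culture, of depth and of a shared technical difference were chosen after the results were seen, and those of other splits and of a stronger response were not. The library to which the test of a stronger response was applied was itself picked from the results.

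The effect of CDK-TCIP1 against the mean of Neg1 and Neg2 differed between 4 h and 2 h for 2200 genes, and for 47 of 125 named genes (edgeR quasi-likelihood test of the difference itself, in 3 and 4 CDK-TCIP1 libraries with 4 comparison libraries at each time). Many named genes were picked by their change at 4 h or between 2 h and 4 h in these data, which can raise their share. Values here are the difference over time on the log2 scale, given for 46 of the 47. Positive ones belonged to AFF1 (2.16), ACTA2 (1.81), ZBED6 (1.46), KLHL25 (1.28), ZNF324B (1.21), BBC3 (1.09), FAS (1.07), TNFRSF10D (1.04), INKA2 (0.94), TNFRSF10B (0.90), ZMAT3 (0.81), FOXO3 (0.80), CDKN1A (0.76), GCNA (0.66), CCNL2 (0.55), CCNE2 (0.53), TRIM22 (0.46), MCL1 (0.44), BCL2L11 (0.40), BTG2 (0.33), IER5 (0.33), CCNT1 (0.30), BIRC2 (0.29), KIF23 (0.28), MYBL1 (0.26) and PLCG2 (0.19). Negative ones belonged to KLHL14 (-1.68), ZPBP2 (-1.42), SERPINA9 (-1.30), PRIMA1 (-1.23), ITPR1 (-1.17), HEATR3 (-1.03), SCIMP (-0.99), PRKCH (-0.80), B3GNT6 (-0.79), CD27 (-0.78), PUS7 (-0.59), BLNK (-0.54), POLR2A (-0.54), LCK (-0.53), FNDC1 (-0.45), HMMR (-0.42), DCN (-0.34), UTP20 (-0.32), DLGAP5 (-0.31) and BIRC6 (-0.30).

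Many genes were called at 2 h against DMSO libraries that had been harvested at 4 h, so the extra time in culture may have taken part. It would predict that the changes shrink against Neg1 and Neg2 of 2 h. For the 6062 genes called at 30 nM the median ratio of the change against those libraries to the change against DMSO was 0.937, and 6048 genes (99.8%) had the same sign, which argues against time in culture as the cause of the pattern as a whole. An effect of time on single genes stays open.

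At 100 nM and 2 h, replicate 1 lay apart from the other libraries of its group, at -27.8 on the second principal component against -13.5 and -13.3. Lower depth is argued against, since its total of 20.672 M estimated counts was the highest of the group. The deviations of this library and of Neg2 2 h replicate 1 had a correlation of -0.078 over 10086 genes with an average log2 CPM of at least 2. The bulk of genes at that level therefore showed no shared shift. A technical difference shared by both libraries stays open, since the correlation leaves out the less abundant genes. They had the fewest genes with any counts of all libraries, 22965 and 22970. Each also had the highest share of mitochondrial mRNA in its group, 6.84% and 5.91% of the counts. A stronger response of the same kind in 100 nM replicate 1 may have taken part and stays open. Its deviation had r = 0.255 with the change from 10 to 30 nM. However, r was 0.119 with the effect at 30 nM and 2 h and -0.223 with the change from 2 to 4 h. No biological difference within a group is given by the design, so none was tested.

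In the 4 libraries at 30 nM and 2 h, the only group of that size, 9 of 130 values had 1 library far from the others (the gap to the nearest library over the range passed the 95% critical value of Dixon). Chance flags about 1 in 20 groups. FAS was at 6.04 CPM in replicate 4 and 9.62 to 10.1 in the others (ratio 0.881), HSPA1A at 6.93 in replicate 1 against 12.3 to 13.2 (0.86), CCNE2 at 17 in replicate 1 against 19.5 to 20 (0.839) and MALT1 at 80.5 in replicate 2 against 82.4 to 82.8 (0.834). BBS12 was at 3.77 in replicate 4 against 2.55 to 2.75 (0.833), PLPP6 at 5.29 in replicate 2 against 3.12 to 3.45 (0.849), MYBL1 at 392 in replicate 3 against 354 to 355 (0.983) and RPS15 at 1880 in replicate 2 against 1720 to 1740 (0.876). The library total was highest in replicate 1, at 26373153 estimated counts, against 19754750 to 19970839 (0.967).

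Transcripts outside the annotation used for gene totals also responded. Of 3605 such transcripts tested, 53 were called for CDK-TCIP1 at 30 nM and 4 h against DMSO (36 higher, 17 lower), 41 at 30 nM and 2 h, 77 at 100 nM and 6 at 10 nM, and at most 1 for Neg1 or Neg2 at either time (edgeR; 140 to 164 at an unadjusted p under 0.05).

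Other splits of the libraries were counted for the comparisons with at least 3 libraries in each group, with only those groups in the fit. For 30 nM and 2 h against DMSO, 1 of 35 splits, the real one, called as many genes (6369, highest of the others 1). The same held for 4 h against 2 h (1 of 35 splits, 4119 and 131 genes) and for 100 nM against 30 nM (1 of 35 splits, 1456 and 2 genes). For each of these 3 the share of splits was under 0.05, with no adjustment over the comparisons. All 3 use the same 30 nM 2 h libraries. If replicates were not separate cultures, a chance difference between cultures is not excluded. For 30 nM and 4 h (6738 genes, highest of the others 0) and for 100 nM against DMSO (6891 and 0), the 10 splits are too few for a share under 0.05.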

How the results depend on the processing

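Scaling by library size alone and the fit without 100 nM replicate 1 and Neg2 2 h replicate 1 were chosen after seeing the data, and the other alternatives before. Of up to 243 results for named genes, 241 kept their direction and side of the threshold with DESeq2, 242 with its size factors in edgeR, 237 with no filter, 240 with library size alone, 237 without the 2 libraries, 232 with only the groups compared and 208 with length-scaled counts, where 28 lost their call and 6 changed sign. Length scaling raised the median dispersion from 0.0196 to 0.0475; further causes were not tested. Depth limits the low genes. In simulated data at 30 nM and 4 h, 52.5% of 2-fold changes were recovered over all genes. At an average log2 CPM of at least 2 the share was 89.1%. Only 200 genes were changed there, so the adjusted threshold was harder to pass than with the 6531 genes called in the real comparison. These shares are therefore not the power of the real comparison.

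Counts that moved over 1.5 times were, with length scaling, 990 at 10 nM, 4035 at 30 nM and 2 h, 2861 and 3351 against Neg1 and Neg2 at 2 h, 3420 and 3386 against them at 4 h, 1887 for 4 h against 2 h, 91 and 837 for the dose steps and 642 for the difference over time. With no filter, Neg1 and Neg2 against DMSO had 4 and 15 called genes at 4 h and 9 and 26 at 2 h, and Neg2 against Neg1 had 24 at 2 h and 2 at 4 h. With only the groups compared, these counts were 6, 54, 10, 1, 11 and 12, and the upper dose step had 1456. DESeq2 gave 1 for Neg1 at 4 h, 3 and 1 for Neg1 and Neg2 at 2 h, 1 for Neg2 against Neg1 at either time and 824 for 10 to 30 nM. Without the 2 libraries, Neg2 at 2 h had 1, Neg2 against Neg1 at 2 h had 1, and the dose steps had 927 and 971. With a preset correlation of 0.01 the lists called were 10 at 30 nM and 4 h, 9 at 30 nM and 2 h, 10 and 9 against Neg1 and Neg2 at 4 h, 9 and 7 against them at 2 h, 5 and 9 at 10 and 100 nM, 6 and 6 for the dose steps, and 9 and 9 for 4 h against 2 h and the difference over time. For Neg1 and Neg2 against DMSO they were 4 and 5 at 4 h and 0 and 1 at 2 h, and for Neg2 against Neg1 3 at 2 h and 1 at 4 h. A preset of 0.01 treats the genes of a list as nearly independent, and whether this alone gave the higher counts was not tested.

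Leaving out single libraries gave 5633 to 5908 genes at 30 nM and 4 h, 1041 to 1932 at 10 nM, 5061 to 5761 at 30 nM and 2 h, 6720 to 7261 at 100 nM, 3074 to 4678 and 3286 to 5208 against Neg1 and Neg2 at 2 h, 3618 to 5036 and 3790 to 5053 against them at 4 h, 3066 to 3669 for 4 h against 2 h, 77 to 482 and 869 to 2849 for the dose steps and 1660 to 2470 for the difference over time. Neg1 and Neg2 against DMSO had 0 to 1 at 4 h and 0 to 1 and 0 to 93 at 2 h, and Neg2 against Neg1 had 0 to 89 at 2 h and 0 to 1 at 4 h. The lowest counts came without 10 nM replicate 1 (1041; 1258 without replicate 2) or replicate 2 (77; 150 without replicate 1, 302 without 30 nM replicate 4), Neg1 2 h replicate 2 (3074; 3106 without replicate 1), Neg2 2 h replicate 1 (3286), Neg1 4 h replicate 2 (3618) and 100 nM replicate 1 (869), and the 93 and 89 without Neg2 2 h replicate 2. Where a group of 2 lost a library, the other was assumed to vary like the rest.

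Signs that changed were, with length scaling, VANGL1 between 10 and 30 nM (0.014), RRM2B (0.042) and NFKBIZ (-0.017) at 4 h, FAS at 10 nM (-0.037), and CDK9 (-0.072) and CDKN1A (0.138) at 100 nM. With library size alone they were BCL2L11 at 30 nM and 2 h (-0.018) and CDK9 (-0.116) and BBC3 (-0.014) at 100 nM. CDK9 at 100 nM was -0.002 with no filter, -0.018 without DMSO replicate 3 and -0.096 without 100 nM replicate 2 (-0.096 to 0.158 over the libraries left out). BCL2L11 at 10 nM was 0.003 without DMSO replicate 2 (-0.049 to 0.003) and FAS at 10 nM -0.075 without 10 nM replicate 2 (-0.075 to 0.125). The cause was not tested for these signs or for the counts above.

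The replicate numbers of the titles do not pair the libraries. Over 78 pairs with the same number, deviations from the group means had a median correlation of 0.011 (-0.163 to 0.173, 10 of them over 0.1), against -0.009 for other pairs, and 4 of 23 libraries correlated best with their own number. With the replicate number as a block, 4 lists were called at 30 nM and 4 h and 5 and 5 against Neg1 and Neg2, the correlation of effects between 30 and 100 nM was 0.898, PRDM1 at 30 nM and 2 h was at -0.064, and 238 of the 243 gene results kept their side. The block ended the calls of MT-ND3 and CCR7 at 4 h (adjusted p of 0.0584 and 0.0616, edgeR). It also ended those of MCL1 at 30 nM and 2 h (0.128) and SLC19A2 between 10 and 30 nM (0.0989).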

Other observations

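The tests of RNA without a poly(A) tail and of reads moved between copies, the choice of the ribosomal DNA repeat genes and the interval over libraries came after the values were seen, and the test of gene length before.

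Transcripts grouped as those of the ribosomal DNA repeat rose with CDK-TCIP1. Some of them are annotated on chromosomes 2, 16 and 20, outside the repeat, and their sequence was not compared with it here. The summed level of MIR663A, MIR663B, MIR663AHG, LINC00273, MIR3648-1, MIR3648-2, RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3 was 26.04 ± 3.69 CPM in DMSO (n = 3 libraries), 264 ± 18.2 at 10 nM (n = 2), 880.5 ± 68 at 30 nM (n = 4) and 2307 ± 388 at 100 nM (n = 3) after 2 h, and 509 ± 137 at 30 nM after 4 h (n = 3). With Neg1 and Neg2 it was 35.8 ± 5.14 and 20.4 ± 6.64 CPM at 2 h and 26.3 ± 1.02 and 29.3 ± 1.67 CPM at 4 h (n = 2 each). All 9 were called higher at 30 nM and 4 h (edgeR), with a median log2 fold change of 4.75. Identical copies share reads, so the value of a single member is uncertain.

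More carry-over of RNA without a poly(A) tail could give such a rise. Other RNAs of that kind would then rise by at least 0.5 times that median. The 22 with an average log2 CPM of at least 0 had a median log2 fold change of 0.245 (95% interval 0.06 to 0.48; 5 higher, 0 lower). For RNAs of that level this argues against carry-over as the whole cause. Most of the 22 were histone genes, and histone mRNAs with a tail, which would not report carry-over, were not told apart. With the less abundant ones, 88 in all, the median was 0.47 (9 higher, 1 lower). The highest called were H2BC6 (4.16 ± 1.29), SNORD18 (3.91 ± 1.09), RNU2-1 (2.25 ± 0.81) and SCARNA9 (2.15 ± 0.79), and the lower one was RNU6-137P (-3.34 ± 1.01). The 7SK RNA, at 2.34 ± 1.06, did not pass the test. Carry-over of the less abundant RNAs stays open. Reads moved from near-identical copies stay open: the summed level had a log2 ratio of 4.29, but its members were grouped after they were seen to rise, so the sum had to rise with them. A response to CDK-TCIP1 stays open as well, and whether the reads come from pre-rRNA was not tested.

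Long genes may lose more mRNA after 2 h of CDK-TCIP1, so protein-coding genes were put into 4 bins of 2371 or 2372 genes by length. At 30 nM and 2 h against DMSO the median log2 fold change of the longest bin minus that of the shortest was -0.07. The hypothesis had required a difference beyond -0.2. A difference within 0.1 in either direction had been set to count against it. The 95% interval over genes was -0.091 to -0.043. The spread between libraries was wider: from values per library the difference was -0.06 (95% interval -0.153 to 0.034) against DMSO, -0.017 (-0.123 to 0.088) against Neg1 and -0.116 (-0.221 to -0.01) against Neg2. At 4 h, for which no size had been set, it was -0.147 (-0.246 to -0.047), -0.107 (-0.219 to 0.004) and -0.061 (-0.173 to 0.05). From the shortest to the longest bin the medians against DMSO at 2 h were 0.037, -0.025, -0.083 and -0.033 at 30 nM, 0.049, -0.05, -0.134 and -0.026 at 100 nM and 0.002, -0.006, -0.038 and -0.006 at 10 nM, so they did not fall in order of length, while at 4 h they did (0.026, -0.003, -0.078 and -0.122). The medians of Neg1 and Neg2 against the same DMSO libraries at 4 h also fell in order of length. They were 0.015, -0.006, -0.017 and -0.02 for Neg1 and 0.035, -0.001, -0.025 and -0.046 for Neg2. Those medians rest on the same DMSO libraries, so part of the order may come from the DMSO libraries. With Neg1 of 4 h in place of DMSO the medians of CDK-TCIP1 were 0.005, -0.005, -0.073 and -0.108, again in order. With Neg2 of 4 h they were -0.03, -0.016, -0.063 and -0.078, with the shortest bin out of order. Whether the order at 4 h is particular to CDK-TCIP1 stays open. The 2 h value fell short of the required size. With its interval over genes, it lay in the range set to count against the hypothesis. The intervals over libraries, added after the values were seen, left that range, and the one against Neg2 reached beyond -0.2. The value also depends on the comparison group by about as much as its own size, so the hypothesis stays open.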
